A study of Arabidopsis thaliana with 8 samples.

How the data were processed

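Total RNA had been taken with TRIzol from the aerial part of seedlings aged 6 days, kept at 22 °C under 16 h of light and 8 h of darkness per the labels, and cRNA made from 0.5 ug RNA had been labelled with Cy3. Each of 8 samples was hybridised to 1 Agilent array, 2 for each of wild type, sdg8, sdg26 and sdg8 sdg26, and groups and replicate numbers were taken from the sample titles. The series text speaks of 2 experiments, each with 3 RNA sets per genotype, and does not say which set gave which array, so the p-values measure only the spread between these samples. The spot intensity values were made by the authors with Agilent Feature Extraction, version 11.5.1.1 per the file headers and version 9.1 per the submitters' processing notes. The processed signal intensity is background-subtracted by that software, per the file headers, and the median signal and local background intensities are uncorrected.

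The authors also deposited a table of log2 values. Each of its columns differed from log2 of the processed signal of the same array by nearly 1 constant (medians of the difference from the values used here -0.0103 to -0.0067, SD 0.000267 to 0.00762), and its 75th percentile lay within 0.001 of 0. Scale, centring and direction were therefore settled from the comparison, and only the software is not given in the sources used here. The column medians were -2.33, -2.37, -2.30 and -2.30 for replicate 1 and -2.33, -2.32, -2.29 and -2.31 for replicate 2 of wild type, sdg8, sdg26 and sdg8 sdg26. This table served as an alternative.

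From the intensities, log2 of the processed signal minus the 75th percentile of the array's non-control spots was computed. Of 45220 spots per array 43803 were not controls, 0 were saturated and 18 to 83 were non-uniform and set to missing. Spots of a probe were averaged, giving 43603 probes, of which 34110 were well above background on both arrays of at least 1 genotype and were kept. Of 35617 probes with a RefSeq transcript accession, 34285 (96.3%) matched the TAIR10.1 gene table used for names and neighbours, no coordinates of which are given, and 9318 probes had no locus and stayed outside the comparisons. A gene was represented by its kept probe with the highest mean signal, which gave 20620 genes, 6070 of them with several kept probes. Of these, 2 genes missing in a whole genotype were left out and 20618 were tested, 123 of them with a missing value. For 99 genes called in sdg8 other probes existed, and 3 of 114 such probes had the opposite sign. For sdg8 sdg26 these numbers were 264 genes and 15 of 309 probes.

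Depth has no counterpart on these arrays. The number of arrays and the signal over background set the precision. Replicates correlated at 0.987 (wild type), 0.989 (sdg8), 0.991 (sdg26) and 0.985 (sdg8 sdg26), and the SD of the replicate difference was 0.427, 0.409, 0.353 and 0.447. The median standard error of a difference between genotypes was 0.167, and that of the interaction 0.236.

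Differences were tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3, statmod 1.5.0) in 1 fit with genotype as the factor, with 4 residual and 2.81 prior degrees of freedom and Benjamini-Hochberg adjustment within each of 7 comparisons: each mutant against wild type, sdg8 sdg26 against each single mutant, sdg8 against sdg26, and the interaction. Tests were two-sided. The steps were tested on simulated data, with 200 of 20495 genes changed. At log2 changes of 1, 2 and 3 the shares recovered were 52.8%, 96.8% and 97.0% for sdg8, 61.1%, 96.8% and 93.9% for sdg26, and 59.7%, 98.4% and 95.5% for sdg8 sdg26, with 4, 8 and 15 false calls.

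Gene lists were fixed beforehand: 23 lists with 424 genes, on floral repressors, floral activators, floral organ identity, circadian clock, histone methylation and autonomous flowering pathway, carotenoid and apocarotenoid synthesis, aliphatic glucosinolate synthesis, indole glucosinolate synthesis, jasmonate response, salicylate response, NLR immune receptors, brassinosteroid synthesis and response, auxin response, gibberellin synthesis and response, cytokinin response, flavonoid and anthocyanin synthesis, photosynthesis, cell cycle, cold and abscisic acid response, heat shock, rapid stress and touch response, root tissue markers and seed maturation markers. They were tested with camera (preset correlation 0.01) over 20495 genes without missing values, adjusted over 69 tests, and again with an estimated correlation and with fry. Root and seed markers were included because such tissue could enter a seedling sample.

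Named genes followed a fixed rule: SDG8, SDG26, FLC, SOC1 and FT in every comparison; the 8 largest rises and 8 largest falls among called genes whose mutant arrays lay beyond both wild-type arrays; up to 4 members of each list with the smallest p; the 5 largest changes in each direction between mutants and for the interaction; and up to 5 genes of each direction called in both single mutants. Genes outside it are said to have been chosen after their values were seen.

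For overlaps between comparisons with the same wild-type arrays, 100 simulations of unchanged groups gave the value expected from the shared arrays alone. The wild type has 2 arrays, so it could not be split. The alternatives were normexp on the local background (offset 50), quantile normalization, scaling by the median of bright probes, no filter or a filter on all 8 arrays, the mean over probes, eBayes with trend and robust, the replicate number as a block, slide as a block, only the groups compared, a 2-fold minimum, the deposited table and leaving out each array. Normexp had been planned on the mean signal, which was not used here, and was run on the median signal. Normexp with each array's median background, slide as a random block and a crossed replicate number were added after seeing the data. Slide as a block set only wild-type replicate 2 apart. Genotype takes up the slides of the mutant arrays, so neither slide setting can remove a slide difference tied to genotype. Figures were drawn with Python 3.11.15.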

Results

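Transcript levels were measured in the aerial part of 6-day-old Arabidopsis thaliana seedlings on 8 single-colour Agilent arrays. There were 2 arrays for each of 4 genotypes: wild type (Col), sdg8, sdg26 and the sdg8 sdg26 mutant that carries both mutations. SDG8 and SDG26 encode SET-domain histone methyltransferases. The comparisons asked which genes each mutation affects, which genes respond to both in the same or in opposite directions, and how the mutations combine. Levels are log2 signals relative to the 75th percentile of each array. Differences are given with their standard error from 1 limma fit over the 8 arrays (n = 2 arrays per genotype), and a gene is said to have risen or fallen where its adjusted p was under 0.05 among 20618 genes tested. A gene not well above background on either array of a genotype has only a bound, written as at least N-fold. The number of arrays limits the precision. Wild-type replicate 1 lay on slide 1, wild-type replicate 2 on slide 2, both sdg8 arrays on slide 3, and all 4 sdg26 and sdg8 sdg26 arrays on slide 4. Only sdg8 sdg26 against sdg26 lay within 1 slide, and each other comparison also set slides against each other. Between 77.1% and 78.9% of probes were well above background on the arrays of slide 4, and between 72.0% and 74.9% on the other arrays. With normexp background correction on the local background, 0 genes passed limma's test in any of the 7 comparisons, against 270 to 2152 genes at an unadjusted p under 0.05, so every call of a single gene given here was lost under that setting. The highest local backgrounds were 229880 (sdg26 replicate 2) and 23118 (wild-type replicate 1), where the array medians were 26 and 28. With normexp on each array's median background, genes were called in each mutant against wild type.

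SDG8 and SDG26 were low in the mutants named for them. In the wild-type arrays the SDG8 level was -0.50 ± 0.19 (SD, n = 2) and the SDG26 level -1.06 ± 0.04. SDG8 was at -3.40 ± 0.26 in sdg8, -0.43 ± 0.08 in sdg26 and -2.83 ± 0.17 in sdg8 sdg26. SDG26 was at -1.03 ± 0.05 in sdg8, -5.69 ± 0.41 in sdg26 and -4.50 ± 0.71 in sdg8 sdg26. SDG8 was thus 7.50-fold lower in sdg8 (adjusted p = 0.00155) and 5.03-fold lower in sdg8 sdg26 (adjusted p = 0.00226), and differed by 0.06 ± 0.18 in sdg26 (adjusted p = 0.930). SDG26 was 24.8-fold lower in sdg26 (adjusted p = 0.0301) and 10.9-fold lower in sdg8 sdg26 (adjusted p = 0.00440), and differed by 0.03 ± 0.33 in sdg8 (adjusted p = 0.980). Each gene was read by 1 probe, and where the probes lie relative to the mutations is not given in the sources used here. The SDG26 call in sdg26 was lost without wild-type replicate 1 (adjusted p = 0.0990) or 2 (0.0758), sdg8 replicate 1 (0.0677) or 2 (0.0681), and sdg26 replicate 1 (0.177) or 2 (0.239), while its log2 difference stayed between -4.92 and -4.34.

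**Figure D1:**
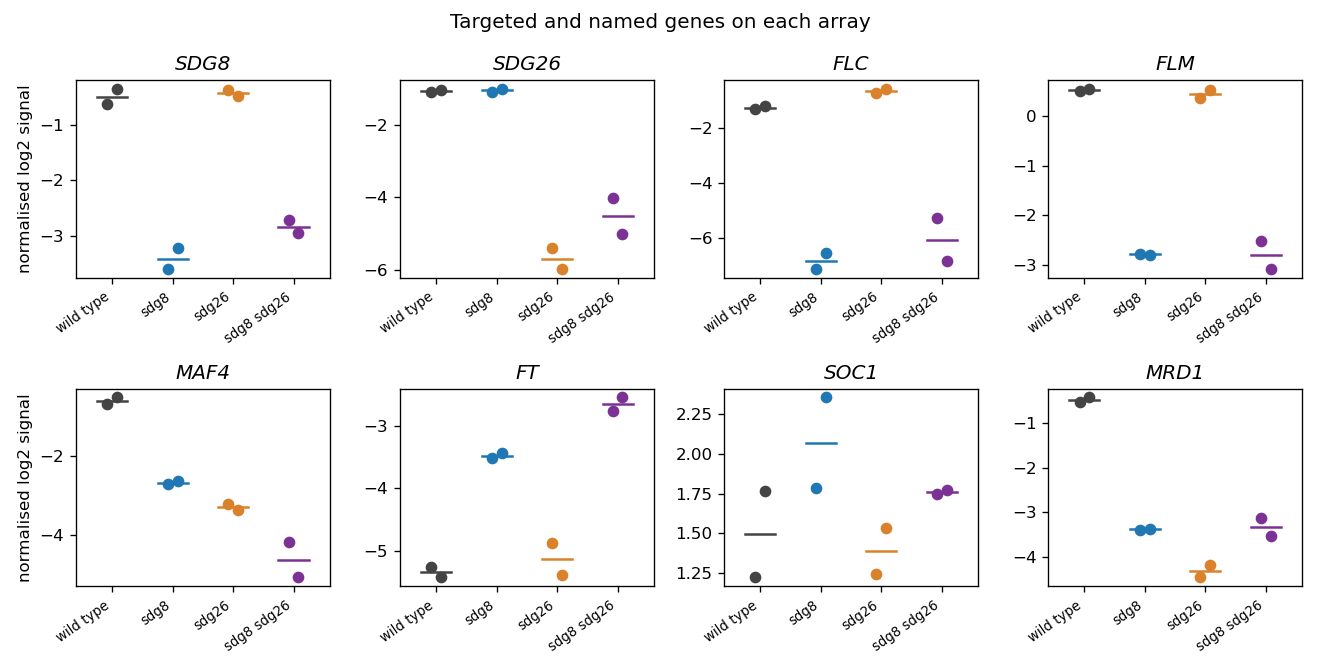
Level of 8 genes on each of the 8 arrays, as log2 signal relative to the 75th percentile of the array; points are arrays and lines are means of the 2 arrays of a genotype. SDG8 stood at -0.50 in wild type and -3.40 in sdg8, SDG26 at -1.06 in wild type and -5.69 in sdg26, and MRD1 lay between -4.33 and -3.34 in the mutant genotypes against -0.47 in wild type.

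The genes that fell in sdg8 included 4 repressors of flowering and 5 immune receptors. FLC, a MADS-box repressor of flowering, was at least 29.8-fold lower in sdg8 (log2 difference -5.53 ± 0.47, adjusted p = 0.00428) and was not well above background on either sdg8 array. Bounds such as this one compare the mean of the bright genotype with the mean of the dim genotype, taking on each dim array the higher of the probe's own signal and the lowest signal among probes well above background. FLM, a related repressor, fell 9.77-fold (-3.29 ± 0.19, adjusted p = 0.00135). FT, the mobile activator of flowering, rose 3.64-fold (1.87 ± 0.19, adjusted p = 0.00758), and SOC1, another activator, differed by 0.58 ± 0.25 (adjusted p = 0.315). The FT call was lost without wild-type replicate 2 (adjusted p = 0.0523) or sdg8 replicate 2 (0.05005). Of 14 floral repressors measured, 0 rose and 4 fell, FLC, FLM, MAF4 and MAF5. Adjusted over the list alone, 2 rose and 5 fell, and the camera test of the list gave an adjusted p of 0.0798 (0.912 with an estimated correlation). MAF4 fell 4.19-fold (-2.07 ± 0.27, adjusted p = 0.0165) and MAF5 2.53-fold (-1.34 ± 0.16, adjusted p = 0.0128). The MAF4 call was lost without wild-type replicate 1 (0.0647) or 2 (0.0928), or sdg8 replicate 1 (0.0870) or 2 (0.0821), and the MAF5 call without sdg8 replicate 1 (0.0574) or 2 (0.0791). Of 15 floral activators 1 rose, FT, and 0 fell, also over the list alone (camera adjusted p = 0.675).

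Among 16 NLR immune receptors, proteins that trigger defence on sensing pathogen effectors, 0 rose and 5 fell in sdg8, and adjusted over the list alone 7 fell. RPM1, a receptor for bacterial effectors, fell 4.37-fold (-2.13 ± 0.15, adjusted p = 0.00278), LAZ5 fell by 1.83 ± 0.23 on the log2 scale (adjusted p = 0.0141), ADR1 fell 2.34-fold (adjusted p = 0.00961) and RRS1 2.28-fold (adjusted p = 0.0117). CHS3, named after its values were seen, fell by 1.69 ± 0.30 on the log2 scale (adjusted p = 0.0393). The list was lower than other genes by camera (median -0.46, adjusted p = 6.3e-05), and its adjusted p was 0.912 with an estimated correlation. RPM1 kept its call without any 1 array. The calls of LAZ5 (adjusted p 0.0565 to 0.0847), RRS1 (0.0516 to 0.0752) and CHS3 (0.107 to 0.175) were lost without either wild-type or either sdg8 array, and that of ADR1 without wild-type replicate 2 (0.0583) or sdg8 replicate 2 (0.0587).

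CRTISO, the carotenoid isomerase, fell 10.1-fold in sdg8 (-3.34 ± 0.42, adjusted p = 0.0140). It was the only one of 17 measured genes of carotenoid and apocarotenoid synthesis to pass, also over the list alone, and the list gave an adjusted p of 0.130 by camera. The CRTISO call was lost without wild-type replicate 1 (0.0670) or 2 (0.0794), or sdg8 replicate 1 (0.0789) or 2 (0.0602). Among 21 genes of aliphatic glucosinolate synthesis, which makes methionine-derived defence compounds, 0 passed over all genes by limma and 5 were lower adjusted over the list alone. The list was lower by camera (median -0.35, adjusted p = 1.1e-04; 0.912 with an estimated correlation), with BCAT4 at -0.85 ± 0.18 and CYP79F1 at -0.51 ± 0.12. Of 18 genes of flavonoid and anthocyanin synthesis, 0 passed over all genes and 0 over the list alone by limma. All 18 values were below wild type, and the list was lower by camera (median -0.47, adjusted p = 6.1e-04, and 0.912 with an estimated correlation). In sdg8 sdg26 against sdg26, on those 4 arrays alone, the flavonoid list had a median of 0.15 (camera adjusted p = 0.244). In sdg8 sdg26 against wild type its median was 0.08 (camera adjusted p = 0.744), with 11 of the 18 values above wild type. Among 21 genes of the rapid stress and touch response, 0 passed over all genes and 6 were lower over the list alone, and the list was lower by camera (median -0.53, adjusted p = 5.4e-04; 0.912 with an estimated correlation). Among 6 floral organ identity genes, 0 passed over all genes and 3 were higher over the list alone, and the list was higher by camera (median 0.59, adjusted p = 0.00671; 0.912 with an estimated correlation). The floral organ identity list lost its call among genes well above background on all 8 arrays (0.0661) and turned to lower with normexp on the local background (0.991).

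IBH1, a repressor of brassinosteroid responses, rose by 1.02 ± 0.15 (adjusted p = 0.0212), the only one of 21 genes of brassinosteroid synthesis and response to pass (camera adjusted p = 0.148), and its call was lost without either wild-type array (0.0890 and 0.0871) or either sdg8 array (0.0945 and 0.112). Of 14 root tissue markers 1 fell, the iron transporter IRT1 (-1.45 ± 0.18, adjusted p = 0.0128), while 3 rose and 1 fell over the list alone (camera adjusted p = 0.331). The IRT1 call was lost without wild-type replicate 1 (0.0603) and without sdg8 replicate 1 (0.0587) or 2 (0.0785). The 15 seed maturation markers measured had a median of -1.20 (camera adjusted p = 0.0502), with 0 called over all genes by limma. Their levels also differed between arrays of a genotype: the albumin gene SESA1 was at 0.17 and -4.11 on the wild-type arrays and at -8.01 and -5.09 on the sdg8 arrays.

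Among all genes, 553 were called in sdg8 against wild type, 167 higher and 386 lower, and 388 of them changed at least 2-fold. At an unadjusted p under 0.05 there were 3440, against 1031 by chance. AT3G28899 (at least 150-fold higher, adjusted p = 4.7e-05), AT3G61030 (at least 32.0-fold higher, adjusted p = 3.6e-05) and QQS, an orphan gene that affects starch content (23.5-fold, 4.56 ± 0.21, adjusted p = 5.6e-04), rose most. AT4G19870 fell 18.0-fold (-4.17 ± 0.33, adjusted p = 0.00377; measured on 1 of the 2 sdg8 arrays), AT4G19865 was at least 8.43-fold lower, AT3G52680 at least 8.47-fold lower and AT3G26922 at least 6.54-fold lower. These 7 genes kept their calls without any 1 array. Other large changes rested on dim signals, such as AT5G37280 (at least 5.54-fold higher), whose call was lost without sdg8 replicate 2 (0.050001) and whose value was -0.0063 with normexp on the local background, and AT1G62085 (at least 12.0-fold lower), whose call was lost without wild-type replicate 2 (0.0634) and without sdg8 replicate 1 (0.0546) or 2 (0.0573). For 117 called genes 1 of the genotypes was below background, and for 23 both were. Left-out arrays lowered the count to 268 (without wild-type replicate 1), 152 (wild-type 2), 135 (sdg8 1), 153 (sdg8 2), 342 (sdg26 1) and 340 (sdg26 2). With normexp on each array's median background it was 292, without a filter on dim probes 222, with only the 4 arrays compared 215, and with slide as a random block 470.

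Few genes were called in sdg26. Besides SDG26, only MRD1, named for its lower transcript in a methionine over-accumulating mutant, passed over all genes (14.5-fold lower, -3.86 ± 0.17, adjusted p = 0.00260), and its call was lost without sdg26 replicate 1 (0.0513). FLC differed by 0.61 ± 0.47 (adjusted p = 0.724), FT by 0.21 ± 0.19 (adjusted p = 0.771) and SOC1 by -0.11 ± 0.25 (adjusted p = 0.913). MAF4 was at -2.68 ± 0.27 and MAF5 at -1.24 ± 0.16 (adjusted p = 0.0666 and 0.135). They were the 2 floral repressors, of 14 measured, that were lower adjusted over the list alone, with 0 over all genes (camera adjusted p = 0.783). The standard errors pool the spread of all 4 genotypes. FLC had an SD of 0.07 in wild type and 0.10 in sdg26, but 0.41 in sdg8 and 1.11 in sdg8 sdg26. It stood at -1.33 and -1.23 on the wild-type arrays and at -0.75 and -0.60 on the sdg26 arrays. MAF4 stood at -0.69 and -0.52 on the wild-type arrays and at -3.20 and -3.36 on the sdg26 arrays. The missing calls therefore do not show that FLC and MAF4 were unchanged in sdg26. The count of 2 genes, both lower, came with 1848 genes at an unadjusted p under 0.05 against 1031 by chance. It was 7 without wild-type replicate 1, 5 without wild-type replicate 2, 0 without sdg26 replicate 1, 1 without sdg26 replicate 2 or either sdg8 array, and 4 without either sdg8 sdg26 array. It was 5 with quantile normalization (1 higher, 4 lower), 6 with normexp on the median background (1 higher, 5 lower) and 2 with slide as a random block.

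By camera 6 lists shifted in sdg26, though no list member passed over all genes by limma. With an estimated correlation none of the 6 was called, at an adjusted p of 0.950 for photosynthesis and 0.912 for the other 5. The cell cycle genes were higher (17 measured, 2 higher over the list alone, median 0.25, adjusted p = 3.2e-04), a call lost without sdg26 replicate 1 (0.102). The salicylate response genes, markers of defence, were higher (16 measured, 2 higher over the list alone, median 0.21, adjusted p = 0.00402), with PR1, below background in wild type, at least 2.78-fold higher (adjusted p = 0.308). The list call was lost without sdg26 replicate 2 (0.0553) and with normexp on either background (0.2496 and 0.1019). The photosynthesis genes were lower (27 measured, 0 over the list alone, median -0.22, adjusted p = 3.2e-04). That call was lost without sdg26 replicate 1 (0.288), without wild-type replicate 2 (0.686) and with quantile normalization (0.861). Genes of carotenoid and apocarotenoid synthesis were lower (17 measured, 0 over the list alone, median -0.11, adjusted p = 0.0173), a call lost without wild-type replicate 2 (0.317), without sdg26 replicate 2 (0.0637), without a filter on dim probes (0.0791) and with quantile normalization (0.186). The root tissue markers were higher (14 measured, 2 higher over the list alone, median 0.35, adjusted p = 0.00122), a call lost with normexp on either background (0.441 and 0.246). The seed maturation markers were lower (15 measured, 0 over the list alone, median -1.86, adjusted p = 2.4e-05), a call lost without wild-type replicate 1 (0.0549). SESA1 was at 0.17 and -4.11 on the wild-type arrays and at -8.03 and -3.91 on the sdg26 arrays.

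In sdg8 sdg26 FLC, FLM and MAF4 were again low, and FT was high. FLC was 27.1-fold lower (-4.76 ± 0.47, adjusted p = 0.00462; measured on 1 of the 2 sdg8 sdg26 arrays), FLM 9.87-fold (-3.30 ± 0.19, adjusted p = 9.9e-04) and MAF4 16.2-fold (-4.02 ± 0.27, adjusted p = 0.00147). FT rose 6.43-fold (2.69 ± 0.19, adjusted p = 0.00180), and SOC1 differed by 0.27 ± 0.25 (adjusted p = 0.537). FLC, FLM, MAF4 and FT kept their calls without any 1 array. MAF5 fell 2.25-fold (adjusted p = 0.0130; lost without wild-type replicate 1, 0.0586, or sdg8 sdg26 replicate 1, 0.0561). MAF3, named after its values were seen, fell by 0.61 ± 0.13 on the log2 scale (adjusted p = 0.0474; 0.0749 to 0.154 without any 1 array). Of 14 floral repressors 0 rose and 5 fell, also over the list alone, and the list was lower by camera (median -0.23, adjusted p = 0.0196; 0.912 with an estimated correlation). That call was lost without wild-type replicate 1 (0.0907) and with normexp on the local background (0.136). Of 15 floral activators 1 rose, FT, and 1 fell, SPL4 (-1.29 ± 0.27, adjusted p = 0.0409), with 2 higher and 1 lower over the list alone (camera adjusted p = 0.783). The SPL4 call was lost without any 1 array except wild-type replicate 2 (adjusted p 0.0632 to 0.158).

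Of 16 NLR immune receptors 0 rose and 6 fell in sdg8 sdg26, and 10 fell over the list alone. LAZ5 fell 4.95-fold (-2.31 ± 0.23, adjusted p = 0.00462), RPM1 3.24-fold (-1.69 ± 0.15, adjusted p = 0.00393) and RRS1 2.27-fold (-1.18 ± 0.14, adjusted p = 0.00781), and these 3 kept their calls without any 1 array. ADR1 (-0.73 ± 0.13, adjusted p = 0.0291) and, named after their values were seen, CHS3 (-1.43 ± 0.30, adjusted p = 0.0415) and RPP13 (-0.80 ± 0.16, adjusted p = 0.0348) each lost the call without 6 of the 8 arrays, each left out alone (0.0529 to 0.118, 0.0611 to 0.162 and 0.0621 to 0.141). The list was lower by camera (median -0.66, adjusted p = 4.6e-06; 0.912 with an estimated correlation). EDS1, which acts downstream of a class of these receptors, was the only one of 16 salicylate response genes to pass, also over the list alone (-0.92 ± 0.17, adjusted p = 0.0283; camera adjusted p of the list 0.827). The EDS1 call was lost without either wild-type array (0.0780 and 0.104) or either sdg8 sdg26 array (0.0894 and 0.104). Among 24 auxin response genes, 0 passed over all genes by limma, while 1 was higher and 11 lower over the list alone. SAUR65 was at -0.84 ± 0.19 and SAUR21 at -0.59 ± 0.14. The list was lower by camera (median -0.44, adjusted p = 6.1e-04; 0.912 with an estimated correlation).

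CRTISO fell 21.8-fold in sdg8 sdg26 (-4.44 ± 0.42, adjusted p = 0.00415) and kept its call without any 1 array. BCH2, a carotene hydroxylase, fell by 0.58 ± 0.11 (adjusted p = 0.0313; 0.0614 to 0.117 without any 1 array). Of 17 genes of carotenoid and apocarotenoid synthesis these 2 fell, 4 over the list alone, and the list was lower by camera (median -0.13, adjusted p = 0.0169; 0.912 with an estimated correlation). That call was lost without wild-type replicate 2 (0.128), with quantile normalization (0.119) and with normexp on the local background (0.190). The photosynthesis genes were lower by camera (27 measured, 0 over all genes by limma and 0 over the list alone, median -0.26, adjusted p = 0.00331; 0.950 with an estimated correlation). That call was lost without wild-type replicate 2 (0.430), without sdg8 sdg26 replicate 2 (0.120), with quantile normalization (0.814) and with normexp on the local background (0.464).

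The rapid stress and touch response list was lower in sdg8 sdg26 by camera (21 measured, median -0.33, adjusted p = 0.00824; 0.950 with an estimated correlation). SZF1 was its only member to pass, also over the list alone (-1.18 ± 0.22, adjusted p = 0.0307). The list call was lost without wild-type replicate 2 (0.180), without sdg8 sdg26 replicate 2 (0.0536) and with normexp on the local background (0.0925). The SZF1 call was lost without either wild-type array (0.0580 and 0.105) or either sdg8 sdg26 array (0.0955 and 0.110). The cold and abscisic acid response list was lower (16 measured, median -0.39, adjusted p = 0.0104; 0.950 with an estimated correlation), with CBF1 the only member to pass, also over the list alone (-1.20 ± 0.19, adjusted p = 0.0186). The list call was lost without wild-type replicate 2 (0.0784), without sdg8 sdg26 replicate 2 (0.0787) and with normexp on either background (0.117 and 0.0565). The CBF1 call was lost without wild-type replicate 1 (0.0820) or sdg8 sdg26 replicate 1 (0.0542) or 2 (0.0829).

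The root tissue markers were higher in sdg8 sdg26. Of 14 measured 2 rose and 0 fell, and 7 rose over the list alone. EXPA7, a root hair expansin, rose 3.27-fold (1.71 ± 0.28, adjusted p = 0.0206) and CASP1, a Casparian strip protein, by 0.97 ± 0.20 (adjusted p = 0.0420). PYK10, a root glucosidase named after its values were seen, differed by 0.13 ± 0.17. The list was higher by camera (median 0.78, adjusted p = 5.4e-04; 0.912 with an estimated correlation). Its call was lost with normexp on the median background (0.0761) and turned to lower with normexp on the local background (0.864). The EXPA7 call was lost without either wild-type array (0.106 and 0.0619) or either sdg8 sdg26 array (0.0697 and 0.0870), and the CASP1 call without any 1 array (0.0507 to 0.148). The 15 seed maturation markers had a median of -0.82 (0 called by limma, camera adjusted p = 0.577), with SESA1 at -3.44 and -6.65 on the sdg8 sdg26 arrays.

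Among all genes, 1290 were called in sdg8 sdg26 against wild type, 632 higher and 658 lower, 706 of them at least 2-fold, with 5392 at an unadjusted p under 0.05 against 1031 by chance. AT3G28899 (at least 209-fold, adjusted p = 6.2e-05), QQS (96.4-fold, 6.59 ± 0.21, adjusted p = 8.5e-05), AT5G35375 (at least 19.8-fold, adjusted p = 3.2e-04), AT5G53230 (by at least 4.16 on the log2 scale, adjusted p = 0.00173) and AT3G61030 (at least 12.0-fold, adjusted p = 8.5e-05) rose most. AT1G62085, measured on 1 of the 2 sdg8 sdg26 arrays, was at least 17.9-fold lower (adjusted p = 0.00415), AT5G05040 fell 11.9-fold (adjusted p = 3.2e-04), and AT5G56370 was at least 4.18-fold lower (adjusted p = 0.00145). These genes kept their calls without any 1 array, whereas AT5G36805 (lower by at least 2.04 on the log2 scale) lost its call without sdg8 sdg26 replicate 1 (0.0672) or 2 (0.0731). The count was 413 without wild-type replicate 1, 546 without wild-type replicate 2, 853 without either sdg26 array, 617 without sdg8 sdg26 replicate 1 and 524 without sdg8 sdg26 replicate 2. It was 2165 with normexp on the median background (753 higher, 1412 lower), 727 without a filter on dim probes, 497 with only the 4 arrays compared and 1064 with slide as a random block.

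Other genes called in sdg8 sdg26 belonged to lists without a camera call in that mutant. The clock gene ELF4 rose by 1.82 ± 0.40 (adjusted p = 0.0491), as the only one of 19 circadian clock genes (0 over the list alone), and the brassinosteroid genes BR6OX1 (1.41 ± 0.22, adjusted p = 0.0171) and BR6OX2 (0.51 ± 0.11, adjusted p = 0.0491) rose among 21, with 2 higher and 1 lower over the list alone. In the jasmonate response list of 26 genes, AOC3 (1.40 ± 0.26) and OPR3 (0.65 ± 0.13), enzymes of jasmonate synthesis, rose, and LOX4 (-0.90 ± 0.17) and CLH1 (-0.85 ± 0.12) fell, also over the list alone. MAM3, of aliphatic glucosinolate synthesis, rose 2.37-fold (adjusted p = 0.00960), SHP2, a floral organ identity gene measured on 1 of the 2 wild-type arrays, at least 1.98-fold (adjusted p = 0.00960), GA2OX2, a gibberellin-inactivating enzyme, by 0.95 ± 0.16 (adjusted p = 0.0240) and CYCD3;1, a D-type cyclin, by 0.55 ± 0.12 (adjusted p = 0.0453). VRN1, a vernalization factor, fell by 0.74 ± 0.11 (adjusted p = 0.0171). SHP2 kept its call without any 1 array and lost it with normexp on the median background. With normexp on the local background SHP2 (-1.17), ELF4 (-0.35), AOC3 (-0.61), BR6OX1 (-0.013) and GA2OX2 (-0.40) turned to lower, with no call. All of these genes but SHP2 lost their calls without some arrays: MAM3 without wild-type replicate 1 (0.0566), CLH1 without wild-type replicate 1 (0.0602) or sdg8 sdg26 replicate 2 (0.0565), and BR6OX1 without either wild-type array (0.0853 and 0.0675) or sdg8 sdg26 replicate 1 (0.0561). AOC3 lost its call without wild-type replicate 1 (0.117) or either sdg8 sdg26 array (0.0774 and 0.118), and GA2OX2 (0.0504 to 0.108) and VRN1 (0.0536 to 0.0820) without any wild-type or sdg8 sdg26 array. LOX4 lost it without any 1 array except sdg8 sdg26 replicate 1 (0.0521 to 0.121), and ELF4 (0.0518 to 0.154), BR6OX2 (0.0835 to 0.174), OPR3 (0.0634 to 0.136) and CYCD3;1 (0.0784 to 0.163) without any 1 array.

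The camera adjusted p values in sdg8, sdg26 and sdg8 sdg26 were 0.783, 0.646 and 0.577 for the circadian clock, and 0.148, 0.922 and 0.862 for brassinosteroid synthesis and response. They were 0.219, 0.130 and 0.963 for the jasmonate response. For gibberellin synthesis and response (19 measured) they were 0.922, 0.783 and 0.848, for the cytokinin response (9 measured) 0.922, 0.546 and 0.298, and for heat shock (11 measured) 0.646, 0.425 and 0.819. The indole glucosinolate synthesis (7 measured) gave 0.884, 0.679 and 0.675, and histone methylation and autonomous flowering pathway genes (32 measured) 0.601, 0.469 and 0.734. In lists without a call the median, the mean and the camera direction could differ in sign. This held for floral activators, circadian clock and gibberellin genes in sdg8. In sdg26 it held for floral repressors and for circadian clock, brassinosteroid, auxin and gibberellin genes, and in sdg8 sdg26 for aliphatic glucosinolate, gibberellin and heat shock genes. Over the 69 list tests camera with a preset correlation of 0.01 gave 19 calls, camera with an estimated correlation 0, and fry 0 for a common direction and 27 for changes in either direction.

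Genes responding to both single mutations were asked for by the title of the series. Only MRD1 was called in sdg8 and sdg26 in the same direction: it fell 7.53-fold in sdg8 (-2.91 ± 0.17, adjusted p = 0.00143), 14.5-fold in sdg26 and 7.31-fold in sdg8 sdg26 (-2.87 ± 0.17, adjusted p = 0.00105). Each of these falls was measured against the same 2 wild-type arrays, whose slides hold no mutant array. Within slide 4 MRD1 was not lower in sdg8 sdg26 (-3.14 and -3.54) than in sdg26 (-4.47 and -4.19). Independent lists as long as the calls in sdg8 and in sdg26 would share 0.0374 genes. Simulated unchanged groups against the same wild-type arrays shared 0, but almost no calls are expected in such groups, so this is no baseline. The number shared was 0 without sdg26 replicate 1, 7 without wild-type replicate 1, 4 without wild-type replicate 2 and 2 without either sdg8 sdg26 array. At an unadjusted p under 0.05, 562 genes moved the same way, against 249 in the simulation and 146 for independent lists. Part of the excess may come from the shared wild-type arrays. The simulated groups were unchanged, so 1031 genes each are expected at that p, where 3440 and 1848 were found. The value of 249 thus comes from shorter lists. Across genes, which are not independent replicates, the differences in sdg8 and sdg26 correlated at 0.347 (0.501 in the simulation), with a covariance of 0.0593 against 0.0310 simulated.

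Genes moving in opposite directions numbered 0 at limma's adjusted threshold. Only SDG26 and MRD1 were called in sdg26, and independent lists of the called lengths would give 0.0162, so this 0 says little. At an unadjusted p under 0.05 they numbered 121, where the simulation gave 6.54 and independent lists 162. The simulated lists are shorter, with 1031 genes each expected by chance against 3440 and 1848 found, so 6.54 is no baseline here. Of the 121, 78 were not below background in wild type, sdg8 or sdg26. The following genes were chosen after their values were seen. PP2-A3, a phloem lectin gene, was at -2.18 ± 0.29 in sdg8 and 1.55 ± 0.29 in sdg26 (adjusted p of the direct comparison 0.00264). For AT5G44980 and PR1, the salicylate marker, a fall in sdg8 was not measurable, since both were below background in sdg8. ST4A, a sulfotransferase gene below background in sdg26, was at least 7.15-fold higher in sdg8 than in sdg26 (adjusted p = 0.0165; lost without sdg26 replicate 1, 0.0936, sdg26 replicate 2, 0.104, or sdg8 replicate 2, 0.0758). In all, 653 genes were called in sdg8 against sdg26, 126 higher and 527 lower, with FLC at least 45.4-fold lower (adjusted p = 0.00264) and FT 3.16-fold higher in sdg8 (1.66 ± 0.19, adjusted p = 0.00968). The FT call was lost without sdg8 replicate 1 (0.0588) or 2 (0.0621), and FT turned to lower with normexp on the local background (-0.37, adjusted p = 0.866). The count fell to 166 and 193 without sdg8 replicates 1 and 2, and to 117 and 121 without sdg26 replicates 1 and 2. It was 1279 without a filter on dim probes, where 768 were higher and 511 lower, and 379 with normexp on the median background.

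The sdg8 contrast was measured a second time, in the sdg26 background, with 4 arrays of 1 slide and no array in common. Adding sdg8 to sdg26 lowered FLC 41.3-fold (-5.37 ± 0.47, adjusted p = 0.00414; measured on 1 of the 2 sdg8 sdg26 arrays), CRTISO (-4.33 ± 0.42, adjusted p = 0.00559) and AT5G56370 (at least 4.91-fold, adjusted p = 0.00126). It raised AT3G28899 90.7-fold (6.50 ± 0.21, adjusted p = 1.5e-04), QQS 58.4-fold (5.87 ± 0.21, adjusted p = 1.8e-04) and FT 5.57-fold (2.48 ± 0.19, adjusted p = 0.00245), and AT3G61030 was at least 21.6-fold higher. The CRTISO call was lost without sdg26 replicate 1 (0.0534). In this comparison 455 genes were called, 148 higher and 307 lower. Of the 553 genes called in sdg8 against wild type, 516 (93.3%) had the same direction here, against 68.7% of all genes, and 258 were called in both comparisons in the same direction and 2 in opposite directions. Across genes, which are not independent replicates, the comparisons correlated at 0.555. On these 4 arrays alone, camera called 7 lists, each of which had an adjusted p of 0.864 with an estimated correlation. It called the NLR immune receptors (median -0.76, adjusted p = 4.0e-09), auxin response (median -0.41, adjusted p = 1.3e-05) and the rapid stress and touch response (adjusted p = 2.7e-05) lower and seed maturation markers higher (median 1.04, adjusted p = 7.1e-04). Arrays of a genotype differed by more than this for SESA1, which was at -8.03 and -3.91 on the sdg26 arrays and at -3.44 and -6.65 on the sdg8 sdg26 arrays. The floral repressors (0.0226), cold and abscisic acid response (0.0259) and salicylate response (0.0468) were also lower. The root tissue markers had a camera adjusted p of 0.0714, photosynthesis 0.383 (median -0.05) and carotenoid and apocarotenoid synthesis 0.244 (median -0.02). These lists were called against wild type in sdg26 and in sdg8 sdg26, and both genotypes lie on slide 4. For those calls an effect of sdg26 cannot be told apart from a slide difference. The gene count was 94 and 113 without sdg26 replicates 1 and 2, 287 and 223 without sdg8 sdg26 replicates 1 and 2, 347 with slide as a block, 263 without a filter on dim probes and 171 with only the 4 arrays compared.

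**Figure D2:**
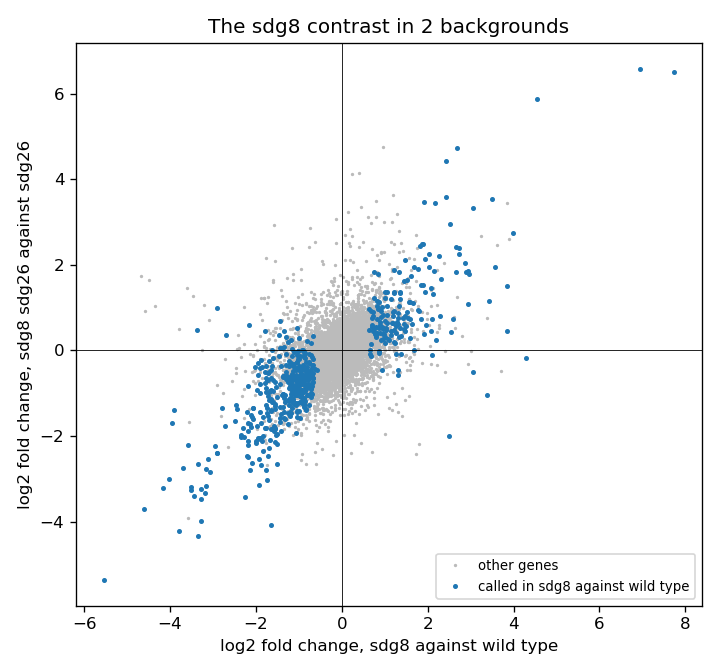
Log2 difference of each gene between sdg8 and wild type (horizontal axis) and between sdg8 sdg26 and sdg26 (vertical axis); grey points are all other genes and blue points the 553 genes called in sdg8 against wild type. Of the blue points 516 lie on the same side of 0 in both comparisons, and the 2 comparisons share no array.

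Adding sdg26 to sdg8 called 58 genes, 42 higher and 16 lower. PP2-A3 rose 7.45-fold (2.90 ± 0.29, adjusted p = 0.0260) and AT3G06895 7.61-fold (2.93 ± 0.28, adjusted p = 0.0237; measured on 1 of the 2 sdg8 arrays), while SDG26 fell 11.1-fold (-3.47 ± 0.33, adjusted p = 0.0234) and AT5G37280 was at least 8.36-fold lower (adjusted p = 0.0170). FT differed by 0.82 ± 0.19 (adjusted p = 0.159). SDG26 lost its call without sdg8 replicate 1 (0.0866) or 2 (0.0885), AT3G06895 (0.0853 to 0.102) and AT5G37280 (0.0747 to 0.0846) without either sdg8 array or sdg8 sdg26 replicate 1, and PP2-A3 without either sdg26 array (0.0633 and 0.0634) or sdg8 sdg26 replicate 1 (0.106). Of the 58 genes, 46 (79.3%) had the same direction in sdg26 against wild type, against 64.7% of all genes. Both comparisons set slide 4 against other slides, so a slide difference could give the same agreement. No comparison for sdg26 lay within 1 slide. The count was 2 and 9 without sdg8 replicates 1 and 2, 26 without either sdg26 array, and 4 and 132 without sdg8 sdg26 replicates 1 and 2. Quantile normalization gave 27 higher and 25 lower, normexp on the median background 46 higher and 56 lower, and 23 were called among genes well above background on all 8 arrays. No gene was called (0 by limma) without a filter on dim probes or with only the 4 arrays compared, with 4026 and 2513 at an unadjusted p under 0.05.

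Of the 553 genes called in sdg8, 387 were also called in sdg8 sdg26 in the same direction and 3 in opposite directions. Independent lists gave 17.44 and 17.16, and the simulation 0.01 and 0. The simulated groups were unchanged and so expected to have almost no calls, which makes them no baseline for these lists. The covariance was 0.185 against 0.0310 simulated, and the wild-type arrays shared by the comparisons may add to the overlap. A further 900 genes were called in sdg8 sdg26 and not in sdg8, SDG26 among them, and 35 of these were called in sdg8 sdg26 against sdg8. Of the 900, 843 had the same direction in sdg8 below the threshold. Of all genes 74.8% had the same direction in these comparisons, which share the wild-type arrays. The median log2 difference of the 900 from wild type, in the direction of the call, was 0.96 in sdg8 sdg26. Over the same 900 genes it was 0.47 in sdg8 and 0.33 in sdg26, measured against the same wild-type arrays. The departure of sdg8 sdg26 from the sum of the single mutants was significant for 1 gene, MRD1 (3.90 ± 0.24 above the sum, adjusted p = 0.0245), with 926 genes at an unadjusted p under 0.05 against 1031 by chance. MRD1 stood at -0.47 in wild type, -3.38 in sdg8, -4.33 in sdg26 and -3.34 in sdg8 sdg26. Its interaction call was lost without wild-type replicate 1 (0.0591) or 2 (0.0687), sdg8 replicate 1 (0.144) or 2 (0.0524), and sdg26 replicate 1 (0.0990) or 2 (0.0697). No gene was called (0 by limma) without sdg8 replicate 1 or 2 or sdg26 replicate 1 or 2, with 1134, 764, 946 and 692 at an unadjusted p under 0.05, and 4 were called without wild-type replicate 1 or sdg8 sdg26 replicate 1.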

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

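The tests of MRD1 given here were chosen after the result was seen, as was MSL4 as a gene to name.

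MRD1 was drawn out because its response differed between the backgrounds: the interaction of sdg8 and sdg26 was 3.90 on the log2 scale, with sdg8 sdg26 at -3.34, sdg8 at -3.38 and sdg26 at -4.33. This call was lost without either wild-type, sdg8 or sdg26 array (adjusted p 0.0524 to 0.144), without a filter on dim probes (adjusted p = 0.122) and with normexp on the local background (log2 value 1.61, adjusted p = 0.986). Loss of a chromosome segment around the gene was argued against, since the largest change of the 4 nearest tested genes over the 3 mutants, that of MSL4 in sdg8, was 0.37. A fault of 1 probe could not be excluded, because MRD1 has 1 probe on the array. Its signal was well above background on both arrays of every genotype, and an effect of the mutations, which the design names, stays open and was not tested. All 3 mutants were set against the same 2 wild-type arrays, which share no slide with a mutant array. A difference particular to the wild-type arrays therefore cannot be told apart from an effect of the mutations on MRD1.

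Signals outside the comparisons came from probes without a locus. Of 5609 such probes kept, 187 were called in sdg8 against wild type (61 higher, 126 lower), 12 in sdg26 (9 higher, 3 lower) and 326 in sdg8 sdg26 (203 higher, 123 lower).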

How the results depend on the processing

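The comparisons, named-gene rule, lists and most alternatives were fixed before the data were examined, while normexp on the median background, slide as a random block and the crossed replicate number were chosen after seeing the data. Left-out arrays leave 1 sample in an arm, which is assumed to vary like the other groups. Signal over background limits dim genes, whose differences are bounds. The cause was not tested unless one is given.

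Normexp on the local background gave 0 calls in all 7 comparisons (unadjusted counts 520, 358, 2152, 1772, 1213, 1122 and 270) and 0 genes shared by sdg8 and sdg26. The highest local backgrounds were 229880 (sdg26 replicate 2) and 23118 (wild-type replicate 1). The lowest log2 values of these arrays were -5.59 and -3.30, against -6.28 and -6.08 with the median background. Whether those spots alone raised the values was not tested. With normexp on the local background the median difference over all genes was -0.13 in sdg8, 0.20 in sdg26, -0.22 in sdg8 sdg26, -0.29 in sdg8 sdg26 against sdg26, -0.28 in sdg8 against sdg26 and -0.23 in the interaction, against -0.016 to 0.030 without it. SDG8 was then at -2.42 in sdg8 (adjusted p = 0.404) and -2.01 in sdg8 sdg26 (0.367), and SDG26 at -1.71 in sdg26 (0.979) and -3.01 in sdg8 sdg26 (0.481). Turns in sign were counted only where a value was called in the main setting or under the alternative, and all came in this setting. In sdg8 they were AT5G37280 (-0.0063), AT5G39493 (-0.18), AT3G27473 (-0.23) and AT3G54530 (-0.49). Between mutants they were FT (-0.37) in sdg8 against sdg26 and AT2G03130 (-0.73) in sdg8 sdg26 against sdg26. In sdg8 sdg26 they were AT1G21528 (-0.0065), AT2G03130 (-0.76), NDB4 (-0.37), SHP2 (-1.17), ELF4 (-0.35), AOC3 (-0.61), BR6OX1 (-0.013) and GA2OX2 (-0.40).

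The counts of calls are given in the order sdg8, sdg26 and sdg8 sdg26 against wild type, sdg8 sdg26 against sdg8 and against sdg26, sdg8 against sdg26, and interaction. With all 8 arrays they were 553, 2, 1290, 58, 455, 653 and 1. Counts more than 1.5 times apart from these were as follows. Normexp on the median background gave 292 in sdg8, 6 in sdg26, 2165 in sdg8 sdg26, 102 against sdg8, 379 in sdg8 against sdg26 and 3 interactions, with 4 genes shared in direction and 1 opposite. Quantile normalization gave 5 in sdg26, 2 interactions and 3 shared genes. No filter gave 222, 727 in sdg8 sdg26, 0 against sdg8 (4026 unadjusted by limma), 263 against sdg26, 1279 in sdg8 against sdg26, 0 interactions (1006 unadjusted) and 2 shared. The filter on all 8 arrays gave 4 in sdg26, 23 against sdg8 and 3 shared, trend and robust 4 in sdg26, 2 interactions and 3 shared, and the mean over probes 5 in sdg26 and 2 shared. Only the groups compared, with fewer samples, gave 215, 4, 497, 0 (2513 unadjusted by limma) and 171, with 2 shared, and the 2-fold minimum 706 in sdg8 sdg26. The deposited table, scaling by bright probes and slide as a block or random block moved no count by more than 1.5 times. The 2 slide settings could not show a slide difference tied to genotype, because genotype takes up the slides of the mutant arrays.

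The replicate block gave 349 in sdg8, 1 in sdg26, 36 in sdg8 sdg26 against sdg8, 435 in sdg8 against sdg26 and 0 interactions (892 unadjusted by limma), and SDG26 in sdg26 was at -4.63 (adjusted p = 0.0502). Whether the number marks an experiment is not given in the sources used here. The main fit used no block because the labels name no shared batch. Replicate differences correlated at 0.145, 0.236 and 0.388 among wild type, sdg8 and sdg26, and at -0.157, -0.350 and -0.402 with sdg8 sdg26. With the numbers of sdg8 sdg26 exchanged, every pair would correlate positively. A shared batch with exchanged numbers can therefore not be told apart from samples that share only a number. A replicate block with the numbers of sdg8 sdg26 crossed gave 1133, 21, 2816, 243, 987, 1339 and 3 calls, with 12 shared and 1 opposite.

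Leaving out 1 array gave 135 to 487 calls in sdg8, 0 to 7 in sdg26, 413 to 873 in sdg8 sdg26, 2 to 132 against sdg8, 94 to 347 against sdg26, 117 to 619 in sdg8 against sdg26, 0 to 4 interactions and 0 to 7 shared genes. Opposite calls stayed at 0. SDG26 in sdg26 ranged from -4.92 to -4.34. The list calls, 19, ranged from 13 (normexp on the local background) to 25 (without sdg8 replicate 2). Of 7867 values of named genes under the alternatives, 472 lost their call, 120 gained one and 14 that were called turned in sign. The other 7261 kept their side of the threshold, and uncalled values that turned in sign were counted among them. Slide as a block was run for sdg8 sdg26 against sdg26 only, list tests were not run with slide blocks or the 2-fold minimum, and the interaction was not run with only the groups compared.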

Other observations

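The tests of slide for all sdg8 calls, of signals near background, of the dimmer sdg8 calls and of root tissue were chosen after the result was seen, as were the neighbouring pairs and FIT as genes to name.

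Genes called in sdg8 tended to lie beside each other. In 36 pairs of neighbouring tested genes both were called in the same direction, against a median of 8 and a highest of 21 in 10000 random placements of the calls (permutation p = 1e-04, the smallest they can give). In sdg8 sdg26 against sdg26, measured on 1 slide, there were 31 pairs against a median of 5. Among the 36, AT3G26922 and AT3G26930 were at least 6.54-fold and 12.1-fold lower in sdg8, and AT4G19865, at least 8.43-fold lower, lay beside AT4G19870 (-4.17). AT5G05040 and AT5G05060 were at -3.28 and -3.19, and the flowering repressors MAF4 and MAF5 at -2.07 and -1.34, whose calls were lost without either sdg8 array and, for MAF4, without either wild-type array (adjusted p 0.0574 to 0.0928). These values are consistent with the hypothesis that loss of SDG8 affects short chromosome regions. Tandem copies that share regulation, or whose transcripts reach each other's probes, may give the same count, and this was not tested.

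The 553 genes called in sdg8 could come from slide 3, which holds both sdg8 arrays and no other. A slide difference as the whole cause was argued against, because 93.3% of the calls had the same direction in sdg8 sdg26 against sdg26, whose arrays share slide 4. Signals near background as the whole cause were argued against by the 66.4% of the calls (367 of 553) well above background on all 8 arrays, although 90.5% of all tested genes were. For the 186 calls not well above background on all 4 wild-type and sdg8 arrays, differences between arrays near background cannot be told apart from an effect of the mutation: 90.3% had the same direction on slide 4, but the share of all calls allowed no less than 80.1%, so this value decided nothing. Variants carried along with the sdg8 mutation that change genes beside SDG8 were argued against as a main source. Among the 100 tested genes on either side of SDG8 only 1 was called, FLM. The median window had 5, and 99.3% of 2061 windows had at least as many as this one. Variants that act on genes elsewhere were not tested, and for FLM itself a carried variant stays open. An effect of the mutation remains a hypothesis, and a slide effect on part of the calls stays open.

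The 900 genes called in sdg8 sdg26 and not in sdg8 could come from slide 4. The test took genes called with 1 sdg8 sdg26 array left out and not in sdg8, rather than the 900 themselves. The left-out array differed from the sdg26 arrays of its slide by a median of 0.58 in the direction of the call. This median was 0.61 for replicate 1 and 0.53 for replicate 2. The bootstrap interval (0.529 to 0.628, 2000 draws) resampled genes and does not measure the spread between arrays. These values argue against slide as the whole cause of such calls. Root tissue in the sdg8 sdg26 samples cannot be told apart from a change of root genes in the shoot: of 14 root tissue markers 13 were above wild type, and 1, FIT, was below by more than its standard error. Collection of the aerial part would remove roots, and an effect of the mutations stays open.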
